A study of Mus musculus with 9 samples.

How the data were processed

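Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in heart muscle cells of CD1 (ICR) mice at postnatal days 1, 14 and 56 (P1, P14 and P56). Each stage had 3 libraries, described as biological replicates per the labels. Per the labels' protocols, cardiomyocytes were isolated from pooled hearts, 12 hearts per sample at P1 and 6 to 7 at P14 and P56, and their nuclei were sorted on the nuclear membrane antigen Pcm1. The growth protocol speaks of surgery without saying whether these hearts had any. The labels give no batch, sex or collection time.

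The authors deposited 2 tables of unnormalised read counts for the 9 libraries. One holds a count per gene at a region around its transcription start site (TSS), whose width is not stated; the other holds a count per peak region of a common peak list. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, BWA 0.7.10, SAMtools 1.3.1, MACS 1.4.0, bedtools 2.26 and featureCounts 1.4.2, with the genome build GRCm38; the notes give no role or order for them and no read filters. How samples were pooled to call peaks is not stated. Every deposited TSS region and peak had a mean of at least 10 counts over the 9 libraries, so regions with lower means could not be analysed here. There were 33844 TSS regions and 25915 peaks. Totals per library were 481217 to 2167369 TSS counts and 316311 to 1217798 peak counts.

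Each table was fitted with edgeR 4.0.16 (R 4.3.3): TMM scaling, edgeR's default expression filter with the stage as group (33747 TSS regions and 25885 peaks remained), 1 coefficient per stage over all 9 libraries, and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The comparisons were P56 with P1 (the main one), P14 with P1 and P56 with P14. A further contrast, called timing here, took the log2 change from P1 to P14 minus that from P14 to P56. Log2 fold changes are given with the standard error (SE) of the fit, and levels as CPM (counts scaled to a common library total) with the standard deviation (SD) over 3 libraries. Single values per library were compared between stages by an exact permutation test of the F statistic over all 1680 assignments of the libraries to stages, in which the smallest possible p is 0.00357; a comparison of 3 libraries with 3 cannot go below 0.1.

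Before the data were examined, 30 gene lists with 756 genes were fixed: 19 of heart biology, 7 of markers of other cell types and 4 technical ones. Also fixed then were the comparisons, the tests, most alternatives and the rule for naming genes. Lists were tested at the TSS with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry, each adjusted over 90 tests. A list's median was also placed among 10000 random lists matched on abundance. Named TSS genes were the 10 largest rises and 10 largest falls from P1 to P56, and up to 5 and 5 in the other comparisons, among genes with an adjusted p below 0.05, a mean count of at least 20 and no overlap between the libraries of the stages. Predicted genes were passed over. In addition came up to 4 members per list with the smallest p, a fixed panel of heart and cell cycle genes, and 5 and 5 peaks by the rule for genes. Where a comparison called 5 or fewer regions all were named, predicted genes included, and these were chosen after their values were seen.

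Gene positions came from a RefSeq annotation of GRCm38.p6, in which 25372 of the TSS gene symbols (75.0%) were found. That annotation gives no strand, so a peak was placed by its distance to either end of a gene and not to the TSS, as had been planned: within 1 kb for the promoter share (5 kb as the alternative) and within 5 kb for assignment to a gene (50 kb as the alternative). The gene nearest to a peak, and whether the peak lay inside or outside genes, were taken from protein-coding genes only. A gene's TSS region can overlap a neighbour's, and the counts carry no strand. GC content was not analysed here.

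Alternatives fixed before the data were seen were DESeq2's size factors, library size without a composition factor, the factors of the other table, no filter, a mean count of at least 20, the DESeq2 1.42.0 Wald test, limma-voom, fits of 2 stages alone, the replicate number as a block, stricter thresholds (an adjusted p below 0.01, or a log2 change beyond 1), and leaving out each library in turn. Those added after seeing the data were loess offsets that remove each library's abundance trend (span 0.3), the share of counts in the top 10% of TSS regions or of peaks as a covariate, all libraries thinned to the shallowest, the fit without both P1 replicate 1 and P56 replicate 2, and DESeq2's size factors for the lists. The fits were tested on simulated counts with 100 regions changed 2-fold and 100 changed 3-fold. In the TSS table the P56 with P1 test recovered 42.0% of the former and 84.0% of the latter, the P14 with P1 test 21.0% and 68.0%, and the P56 with P14 test 24.0% and 69.0%. In the peak table the recovered shares were 15.0% and 66.0%, 13.0% and 67.0%, and 12.0% and 57.0%.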

Results

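The 9 libraries profiled open chromatin in mouse cardiomyocyte nuclei at 3 ages after birth, to follow how accessibility changes as the heart matures. TSS counts per library totalled 1414979 to 2167369 at P1, 481217 to 893032 at P14 and 874639 to 1468352 at P56 (exact permutation p = 0.0143), so P14 was the shallowest stage. Rank correlations of CPM at the TSS were 0.787 to 0.882 within stages and 0.749 to 0.874 between them, so replicates were little closer than stages. The share of TSS counts in the top 10% of regions, a measure of signal over background, was 32.3% ± 0.624 (SD, n = 3) at P1, 34.6% ± 0.636 at P14 and 36.0% ± 0.693 at P56, and no P1 library overlapped a P56 library (exact permutation p = 0.00357, the smallest possible). For peaks the shares were 25.4% ± 1.13, 26.3% ± 0.751 and 28.1% ± 1.60 (exact permutation p = 0.0571). P1 replicate 1 had the lowest peak share (24.1%) and P56 replicate 2 the highest (29.8%).

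**Figure D1:**
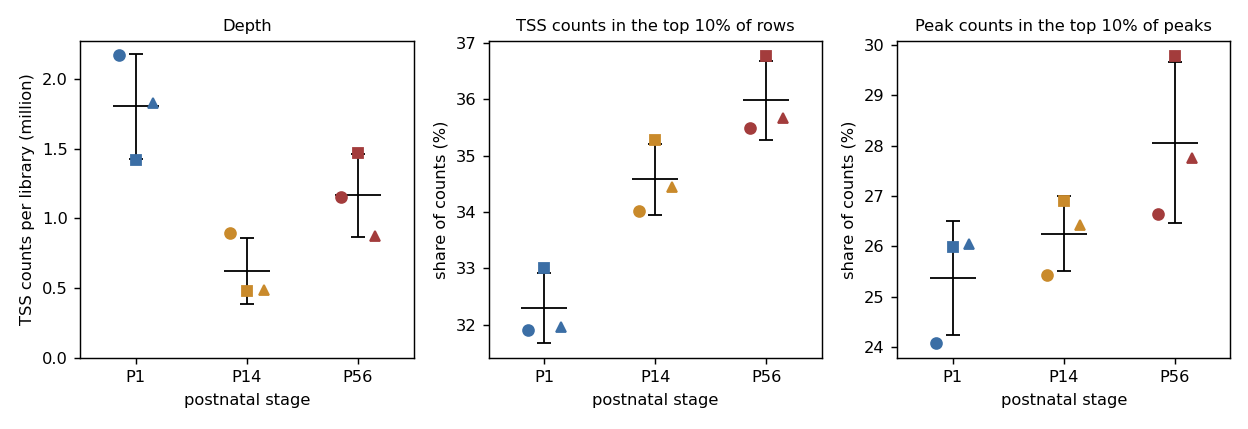
Total TSS counts per library (left), and the share of counts in the top 10% of TSS regions (middle) and of peaks (right), in percent, by stage. Points are libraries (circle, square and triangle for replicates 1, 2 and 3) and bars are means ± SD (n = 3); the middle share rose with age from 32.3% to 36.0%, in step with the stages compared.

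The comparison of P56 with P1 asked which promoters differ between the newborn and the adult heart muscle cell. The TSS of Myh7 (ENSMUSG00000053093, GRCm38 chromosome 14, 54970684 to 54994626), a myosin heavy chain, rose 3.82-fold, from 74.8 ± 28.1 CPM (SD, n = 3) to 283 ± 134. Pnmt (ENSMUSG00000038216, chromosome 11, 98386623 to 98388180), which makes adrenaline from noradrenaline, rose 3.81-fold, from 34.8 ± 5.45 to 131 ± 42.3 CPM, with Tcap 1670 bp away. Nmrk2 (ENSMUSG00000004939, chromosome 10, 81198170 to 81202265), a nicotinamide riboside kinase of muscle, rose 3.36-fold, from 64.2 ± 26.2 to 213 ± 88.4 CPM. Mir133a-2, a muscle microRNA gene, rose from 65.4 ± 23.1 to 232 ± 87.5 CPM.

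The log2 changes of these were 1.93 ± 0.239 for Myh7 (SE, edgeR adjusted p = 4.32e-05), 1.93 ± 0.223 for Pnmt (1.85e-05), 1.75 ± 0.258 for Nmrk2 (0.00054) and 1.85 for Mir133a-2 (0.000135). Other large rises were n-TStga1 (1.80), Sphk2 (1.72, a sphingosine kinase 740 bp from Dbp), Trim72 (1.65, a membrane repair protein of muscle), RP23-64O4.2 (1.48), Ube4a (1.48) and Gpt (1.47, alanine transaminase), with adjusted p between 0.00054 and 0.00645. In all, 581 TSS regions rose and 272 fell. Of 57 named genes called here and in the groups that follow, 19 kept their call whichever library was left out, Myh7, Pnmt, Nmrk2 and Mir133a-2 among them, and 37 lost it without P56 replicate 2, such as n-TStga1 (1.31 without it). Those 4 stayed called without both P1 replicate 1 and P56 replicate 2, at smaller changes (Myh7 1.20, Pnmt 1.48, Nmrk2 1.02, Mir133a-2 1.20). The counts depended on single libraries: 148 were called without P56 replicate 2, 200 and 241 without P1 replicates 2 and 1, 402 without P56 replicate 3, 452, 551 and 496 without P14 replicates 1, 2 and 3, and 1776 without P56 replicate 1. Without both P1 replicate 1 and P56 replicate 2, 471 rose and 181 fell, of which 191 and 79 were shared with the full set. The split moved with scaling, from 68.1% of calls up to 29.1% (319 up, 778 down) with library size and 8.15% (204 up, 2300 down) with the peak table's factors. The median of all regions was -0.14 and -0.30 with these, against -0.01. It was 51.7% with loess offsets (124 up, 116 down).

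**Figure D2:**
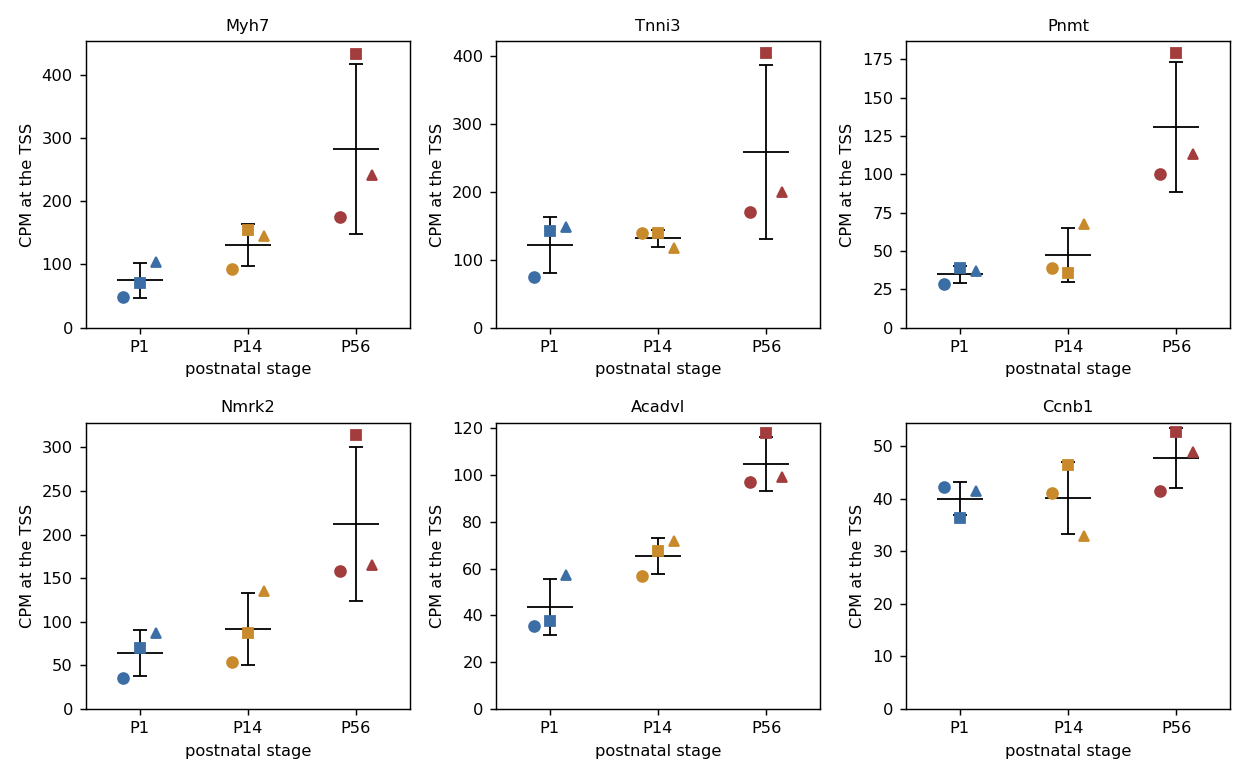
CPM at the TSS per library, by stage, for Myh7, Tnni3, Pnmt, Nmrk2, Acadvl and Ccnb1. Points are libraries (circle, square and triangle for replicates 1, 2 and 3) and bars are means ± SD (n = 3); Myh7 averaged 74.8 CPM at P1 and 283 at P56, while Ccnb1 averaged 40.0 and 47.7.

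Contractile genes rose as a group from P1 to P56. Of 24 mature sarcomere genes, 14 rose and none fell (19 adjusted over the list alone), all 24 had a log2 change above 0, and their median change was 0.82, or 1.77-fold. Among them were Tcap (1.34, titin-cap), Pygm (1.07, muscle glycogen phosphorylase), Ckmt2 (1.42, mitochondrial creatine kinase), Tnni3 (1.11 ± 0.223 SE, adjusted p = 0.00896, cardiac troponin I), Tnnt2 (0.91, 0.0282) and Myh6 (1.03, 0.0354, the adult cardiac myosin heavy chain). Of 20 fetal contractile and stress genes, 4 rose (8 adjusted over the list alone): Myh7, Tnnt1 (1.19), Flnc (1.01) and Acta1 (0.96), with a list median of 0.41. Other fetal and stress genes did not pass: Tnni1 -0.30 (adjusted p = 0.295), Actc1 0.41 (0.453), Nppa 0.25 (0.586) and Nppb 0.79 (0.0588). The TSS regions of Tnnt1 and Tnni3 had similar CPM in every library, such as 84.7 and 73.9 in P1 replicate 1 and 427 and 406 in P56 replicate 2. Whether they count the same reads was not tested, so their rises may not be separate. Camera gave adjusted p = 1.15e-16 for the sarcomere list and 1.17e-05 for the fetal list. It gave 0.56 for both with an estimated correlation. The mean level of the sarcomere list overlapped between stages, at 5.52 to 6.35 log2 CPM in P1 libraries and 6.30 to 7.38 in P56 libraries, the highest being P56 replicate 2 (exact permutation p = 0.2). Without it Tnni3, Tnnt2 and Myh6 lost their calls (0.62, 0.38 and 0.61). Tnnt2 also lost it without P1 replicates 1 or 2 or P14 replicates 1 or 3 and Myh6 without any of the other libraries except P1 replicate 3 and P56 replicate 1. Tcap, Pygm, Ckmt2 and Tnnt1 kept theirs with each library left out, Tnnt1 at 0.66 without P56 replicate 2. Without both P1 replicate 1 and P56 replicate 2, Tcap, Pygm and Ckmt2 were still called at 0.82, 0.57 and 0.87, though Pygm and Ckmt2 are metabolic enzymes. Tnnt1 lost its call there (0.46, adjusted p = 0.0773), as did Tnni3 (0.34, 0.208), Tnnt2 (0.12, 0.728) and Myh6 (0.23, 0.486). There the sarcomere median shrank to 0.23 (adjusted p = 0.00226) and the fetal median to 0.09 (0.0399), both still called, against 0.48 and 0.18 without P56 replicate 2 alone and 0.56 and 0.22 with loess offsets. With the share of top TSS counts as a covariate, which separated these stages completely, the sarcomere list turned lower at P56 (adjusted p = 5.96e-05), and with the peak share it turned lower without passing (0.147). The fetal list lost its call with both (0.377, lower, and 0.976).

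Mitochondrial and fuel gene lists were also called higher at P56. Of 29 genes of oxidative phosphorylation and the TCA cycle, 9 rose (21 adjusted over the list alone), with a median of 0.69 or 1.61-fold and 29 above 0. They included Atp5a1 (1.35, an ATP synthase subunit, 53.1 ± 5.75 to 134 ± 59.7 CPM, SD, n = 3), Cyc1 (1.32, cytochrome c1), Ndufv1 (0.93, complex I) and Cox4i1 (1.05, complex IV). Of 32 fatty acid oxidation genes, 3 rose (7 adjusted over the list alone): Acadvl (1.27, very long chain acyl-CoA dehydrogenase, 43.5 ± 11.9 to 105 ± 11.7 CPM), Ppard (0.77, a lipid-sensing nuclear receptor) and Plin5 (0.88, a lipid droplet protein). Of the others, Cpt1b (0.67, adjusted p = 0.063), Ppara (0.51, 0.201), Ppargc1a (0.09, 0.876) and Esrra (0.69, 0.103) did not pass. Of 26 glycolysis and hypoxia genes, 6 rose (15 adjusted over the list alone), among them Slc2a4 (1.15, the insulin-responsive glucose transporter), Vegfa (0.81), Eno3 (0.95, muscle enolase) and Pfkm (1.09, muscle phosphofructokinase). Camera gave adjusted p = 2.39e-14, 3.41e-06 and 1.98e-09 for the 3 lists, and adjusted p = 0.56 for each with an estimated correlation. Their mean levels per library gave exact permutation p = 0.1 (the smallest possible), 0.5 and 0.1. The fatty acid levels overlapped between stages (5.08 to 5.66 log2 CPM at P1, 5.42 to 6.29 at P56), and the other lists' levels did not. Without P1 replicate 1 and P56 replicate 2, which stood apart in the peak share, the oxidative and glycolysis medians shrank to 0.21 and 0.18 (from 0.69 and 0.51), still called (adjusted p = 0.00237 and 0.0384), while the fatty acid list turned lower without passing (0.63). Without P56 replicate 2 alone these 2 medians were 0.37 and 0.33, and with loess offsets 0.48 and 0.28, with 0.29 for fatty acid genes. The fatty acid list also lost its call without P56 replicate 2 alone (0.123). With each library left out in turn Atp5a1 and Acadvl kept their calls (0.81 and 1.01 without both libraries), and 1 library or more ended those of the other members named here. With the TSS share as a covariate all 3 lists turned lower at P56 (adjusted p = 0.0126, 2.29e-08 and 0.00697), and so they did with the peak share (0.971, 0.000202 and 0.596).

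**Figure D3:**
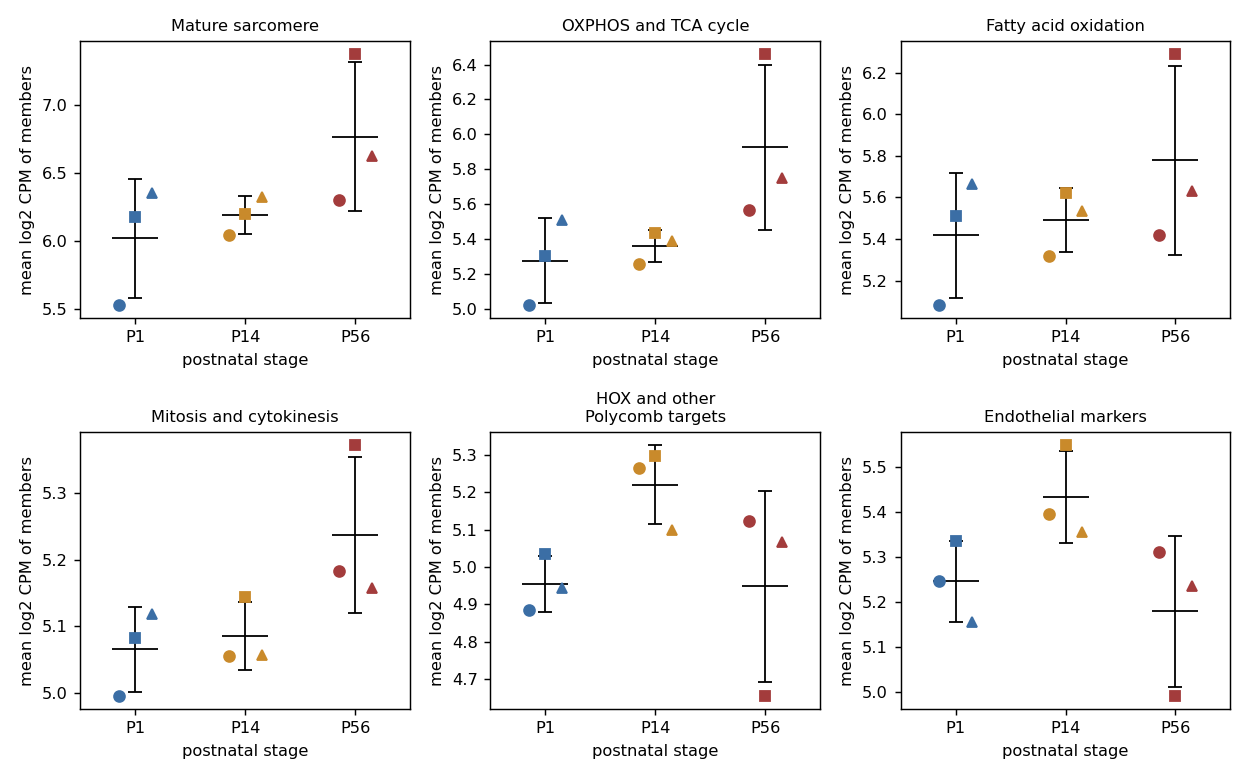
Mean log2 CPM at the TSS over the members of 6 gene lists, per library, by stage. Points are libraries (circle, square and triangle for replicates 1, 2 and 3) and bars are means ± SD (n = 3); in 4 of the lists P56 replicate 2 lay highest, and in the HOX and Polycomb and the endothelial list lowest.

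Ion handling, transcription and clock genes followed, with medians below those of the sarcomere, mitochondrial and fuel lists. Of 37 calcium and ion channel genes, 4 rose (15 adjusted over the list alone), among them Cacna1c (0.61, the L-type calcium channel), Kcnip2 (0.58) and Hrc (1.06, a calcium-binding protein of the sarcoplasmic reticulum). Kcnj2 (0.70, adjusted p = 0.152) and Ryr2 (0.83, 0.11) did not pass. Per1 (0.95), Esrrb (0.66) and Thrb (0.88, a thyroid hormone receptor) rose among 27 thyroid, glucocorticoid and nuclear receptor genes (6 up and 1 down adjusted over the list alone). The circadian clock list had 4 rises among 19 genes (4 adjusted over the list alone), in Ciart (1.21), Per1, Tef (0.88) and Dbp (0.98). Among 29 cardiac transcription factors only Mef2d rose (0.69), here and over the list alone. Camera gave adjusted p = 1.43e-05, 0.00103, 7.02e-05 and 0.0422 for these lists, in the order ion channels, receptors, clock and transcription factors, whose medians were 0.39, 0.31, 0.46 and 0.30. They had adjusted p = 0.56, 0.56, 0.56 and 0.667 with an estimated correlation. The mean level of each list overlapped between P1 and P56 libraries (exact permutation p = 0.3, 0.4, 0.4 and 0.5). With loess offsets the receptor list lost its call (0.357) and the transcription factor list turned lower without passing (0.982), while the ion channel and clock medians, still called, were 0.21 each. Without P1 replicate 1 and P56 replicate 2 all 4 lost it (0.744, 0.985, 0.941 and 0.0949), the receptors and transcription factors turning lower. Single libraries ended calls too: P56 replicate 2 for the clock (0.0549) and the transcription factors (0.779), P1 replicate 1 for the receptors (0.146) and the transcription factors (0.739), and P14 replicate 1 for the latter (0.0524). With the TSS share as a covariate all 4 turned lower (0.0456, 0.0178, 0.000448 and 0.000252), and so they did with the peak share (0.162, 0.0647, 0.0201 and 0.000457). Of the genes named, Ciart kept its call with each library left out (0.86 without both).

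Cell cycle genes, whose expression falls after birth as cardiomyocytes stop dividing, showed no detectable fall in TSS accessibility at P56. None of 32 G1/S and replication genes and none of 35 mitosis and cytokinesis genes passed edgeR's test in either direction, over all genes or over the list alone. The 2 smallest p in each list were those of Gins2 (0.62, adjusted p = 0.123), Mcm2 (0.47, 0.134) for G1/S, and Birc5 (0.70, 0.125) and Cdca8 (0.72, 0.197) for mitosis. Of the members with a change below 0, Cenpe had the smallest p (-0.44, adjusted p = 0.219). From the panel, Ccnb1 had a change of 0.25 (adjusted p = 0.533), Cdk1 0.08 (0.821), Mki67 0.06 (0.909), Aurkb 0.22 (0.528), Ccnd1 0.70 (0.0952) and Ccnd2 -0.04 (0.921). Plk1 was not in the table and was not analysed here. The mitosis list had a median of 0.20, within the central 95% of random lists matched on abundance (-0.00302 to 0.292, percentile 73.7). Camera called it slightly higher (adjusted p = 0.037, or 0.56 with an estimated correlation). That call was lost with library size (0.059), loess offsets (0.64), and without P1 replicate 1 (0.127) or P56 replicate 2 (0.299), and with the TSS and peak shares as covariates it turned lower without passing (0.502 and 0.983). The G1/S list did not pass (median 0.10, adjusted p = 0.298). Among 19 cell cycle inhibitors and checkpoint genes Btg2 rose (1.09, but not called without P56 replicate 2, at 0.77), with 2 genes over the list alone. The list did not pass (adjusted p = 0.0852) but was below 0.05 without P1 replicates 2 or 3 or P56 replicates 1 or 3 (0.0389, 0.0188, 0.015 and 0.0395), and with the TSS and peak shares it was lower and called (0.00121 and 0.0177). Cdkn1a (0.20, adjusted p = 0.546) and Meis1 (-0.17, 0.769), a regulator of postnatal cell cycle arrest, did not pass. Without both P1 replicate 1 and P56 replicate 2, a fit chosen after the data were seen, Meis1 was called lower at P56 (-1.01, edgeR adjusted p = 0.0139). Those libraries held its lowest P1 value (34.8 CPM) and its highest P56 value (69.2 CPM). Leaving them out therefore favours a fall, and the call does not show one.

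Growth and signalling lists moved little. The Wnt list rose (median 0.21, adjusted p = 0.0422, or 0.56 with an estimated correlation) with no member called (Wnt9a 0.81, adjusted p = 0.0717). The call was lost with library size (0.0629), loess offsets (0.982), and without P1 replicate 1 (0.29), P14 replicate 1 (0.0524), P56 replicate 1 (0.18) or P56 replicate 3 (0.107), and with the TSS and peak shares as covariates (0.558 and 0.224). Chromatin regulators rose (median 0.22, adjusted p = 0.00334, or 0.571 with an estimated correlation; Dnmt3a 0.42, 0.052). They turned lower without passing under loess offsets (0.825) and lost their call without P1 replicate 1 (0.0803) or P56 replicate 2 (0.125). They were lower and called with the TSS share (0.0276), and lower without passing with the peak share (0.39). The remaining lists did not pass. They were Hippo and Yap genes (median 0.26, adjusted p = 0.0675, but 0.0401 and 0.0233 without P1 replicates 2 and 3; Tead3 0.56, 0.0534; Yap1 -0.29, 0.537) and growth factor genes (median 0.02, 0.559; Erbb2 0.58, 0.0861). Also among them were the imprinted growth network (median -0.09, adjusted p = 0.566; Igf2bp3 -0.25, 0.465; Lin28b -0.10, 0.894), extracellular matrix (0.07, 0.653, lower and called under loess offsets at 0.0413) and HOX and other Polycomb targets (-0.02, 0.929).

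Of the lists of other cell types, smooth muscle and pericyte markers rose from P1 to P56, with Smtn (0.72, adjusted p = 0.0119) as their called member and a median of 0.21. Camera gave adjusted p = 0.0402 and fry 0.0246, against adjusted p = 0.56 with an estimated correlation and 0.298 with loess offsets. The call was lost without P1 replicate 3 (0.0517), P14 replicate 1 (0.0524), P56 replicate 1 (0.0865) or P56 replicate 3 (0.0649), and with the TSS and peak shares (0.578 and 0.104). Glial and neuronal markers (median 0.31, adjusted p = 0.0707, but 0.0376 and 0.035 without P1 replicate 2 and P56 replicate 2) did not pass. Nor did epicardial (0.19, adjusted p = 0.358), leukocyte (0.11, 0.429), endothelial (-0.01, 0.703; 0.0386 and lower with loess offsets), fibroblast (-0.06, 0.712) and erythroid markers (0.00, 0.929). However, without both P1 replicate 1 and P56 replicate 2 the leukocyte (median 0.23, adjusted p = 0.0183), glial (0.33, 0.0268) and smooth muscle lists (0.26, 0.0308) were called higher at P56, with medians near that of the sarcomere list there (0.23). With the peak share the leukocyte (0.00686) and glial (0.0109) lists were called higher too. Technical lists moved with the heart genes: ribosomal protein genes rose (0.49, adjusted p = 3.41e-06; Rpl18 1.06). So did immediate early genes of cell dissociation (0.46, adjusted p = 1.13e-05; Dusp1 0.96 and Btg2) and proteasome genes (0.29, 0.00334; Psmd12 0.93, 0.0613). Each had adjusted p = 0.56 with an estimated correlation. The single genes Smtn, Rpl18, Dusp1 and Btg2 each lost their call without P56 replicate 2 (0.55, 0.78, 0.49 and 0.77), and without other libraries in turn. The proteasome call was lost without P56 replicate 2 (0.299) and with loess offsets (0.102), and without both P1 replicate 1 and P56 replicate 2 all 3 calls were lost (ribosomal 0.599, immediate early 0.80, proteasome 0.63). With the TSS share as a covariate all 3 turned lower (ribosomal 0.0395, immediate early 0.0055, proteasome 0.0725), and so they did with the peak share (0.37, 0.0647 and 0.483). Y-linked genes did not pass (-0.01, adjusted p = 0.682). The sorting antigen's gene, Pcm1, had a change of 0.33 (adjusted p = 0.563).

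Falls from P1 to P56 lay at weakly covered regions. Named ones were Itgbl1 (-1.34, adjusted p = 0.0304, 22.9 ± 5.00 to 9.77 ± 5.92 CPM, SD, n = 3), Klra17 (-1.33, 0.0167) and Cpb1 (-1.31, 0.0101, 32.0 ± 2.93 to 12.9 ± 1.22 CPM). Others were RP24-351P7.5 (-1.49), Macrod2os2 (-1.19), Mir5127 (-1.16) and the immunoglobulin segments Ighv1-68, Ighv8-12, Ighv1-12 and Ighv10-2 (-1.15, -1.15, -1.15 and -1.14). Of the 272 falls, 56 were in a set of gene families that made up 1511 of the tested regions (Fisher's exact p = 6.23e-22). The set held olfactory, vomeronasal and taste receptors, immunoglobulin and T cell receptor segments, defensins, and keratin-associated and small proline-rich proteins. That test took the regions as independent and was not matched on abundance. Of the falls 43 lay above the median abundance of all regions, against 562 of the 581 rises. DESeq2's Wald test called 3 falls beside 289 rises. Its default filter leaves weakly covered regions without an adjusted p, the named falls among them, so that count does not speak against these falls. Of the named falls Cpb1 kept its call with each library left out. RP24-351P7.5 lost it without P56 replicate 3 (-1.21), Itgbl1 without P1 replicate 1 (-1.18) or P56 replicate 2 (-0.83), Klra17 without P56 replicate 2 (-1.14), and the others without 4 or more libraries in turn.

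From P1 to P14, the earlier interval, 1 annotated gene with a known product rose: Gaa, the lysosomal acid alpha-glucosidase that breaks down glycogen. It went from 119 ± 14.8 to 209 ± 28.8 CPM (SD, n = 3), a log2 change of 0.81 ± 0.149 (SE, adjusted p = 0.0474). The other 3 rises were the gene models Gm10800 (1.38, adjusted p = 0.000395), Gm10801 (1.07, 0.00997) and Gm26917 (0.97, 0.000773), whose counts grew little with library depth. These 4 were the whole set, no region fell, and 2900 had an unadjusted p below 0.05. The DESeq2 Wald test and limma-voom each called 1. The count was 0 without P14 replicate 2 (2025 at an unadjusted p below 0.05), 2 without P14 replicate 3 and 9 without P56 replicate 2. Gaa lost its call without any 1 of the P1 libraries, the P14 libraries or P56 replicate 3 (0.70 to 0.90), and with loess offsets (0.59), library size or DESeq2's size factors. The DESeq2 Wald test did not call it (adjusted p = 0.449).

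HOX and other Polycomb target genes, silent developmental regulators in the heart, rose as a list from P1 to P14 (median 0.37, 29 of 33 above 0, adjusted p = 2.84e-05), with no single member called. Smooth muscle (0.32, adjusted p = 0.00446), glial (0.29, 0.00474), endothelial (0.30, 0.0184), epicardial (0.34, 0.031), Wnt (0.09, 0.0275) and sarcomere genes (0.18, 0.0242) were also called higher. With an estimated correlation the adjusted p was 0.56 for each of these except the sarcomere list, at 0.775. Of the 10 splits of these 6 libraries into groups of 3, 7 gave as large a median for Wnt and 8 for sarcomere genes, counting the real one. For each other list called here only the real split did. The sarcomere direction turned without P1 replicate 1 (0.593) and its call was lost without P14 replicate 2 (0.0763) or P14 replicate 3 (0.183). Other calls were lost without P1 replicate 1 (Wnt 0.333, epicardial 0.0663), P1 replicate 3 (endothelial 0.0647), P14 replicate 1 (Wnt 0.0569, epicardial 0.0902, glial 0.0827) or P14 replicate 2 (Wnt 0.0839, endothelial 0.129, epicardial 0.0763), while the HOX and smooth muscle lists kept theirs. With loess offsets 4 calls ended (endothelial 0.199, epicardial 0.102, Wnt 0.314, sarcomere 0.533). Without both P1 replicate 1 and P56 replicate 2 the epicardial (0.081) and Wnt (0.416) calls ended and the sarcomere list turned lower (0.538). Calls were also gained there: clock (median -0.25, adjusted p = 0.00112), nuclear receptor (-0.21, 0.0132) and cardiac transcription factor genes (-0.15, 0.0113) lower, and leukocyte markers (0.32, 0.0212) higher. The first 3 were lower and called with each covariate as well. The sarcomere list was lower and called with the TSS share as a covariate (1.23e-08), where the Wnt (0.407), endothelial (0.216), smooth muscle (0.279) and epicardial (0.349) calls ended. With the peak share the sarcomere list turned lower without passing (0.152), and the Wnt (0.0794) and epicardial (0.0647) calls ended. The number of lists called was 14 without P1 replicate 3, 4 without P14 replicate 1 and 3 without P14 replicate 2.

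From P14 to P56, Pnmt was the 1 gene that rose, 2.83-fold from 47.5 ± 17.5 to 131 ± 42.3 CPM (SD, n = 3), a log2 change of 1.50 ± 0.247 (SE, edgeR adjusted p = 0.0258). No region fell, and 3402 had an unadjusted p below 0.05; the DESeq2 Wald test called 1 and limma-voom 0 (3082 at an unadjusted p below 0.05). The call was lost without P1 replicate 2, P14 replicate 1, P14 replicate 2, P56 replicate 2 or P56 replicate 3 (0 calls each), and with DESeq2's size factors (adjusted p = 0.0689). The count was 39 without P1 replicate 1, 4 without P1 replicate 3 and 289 without P56 replicate 1. As lists, sarcomere (median 0.72, adjusted p = 6.05e-15), oxidative (0.68, 6.05e-15), clock (0.50, 3.08e-08), glycolysis (0.51, 8.56e-08), fatty acid (0.42, 1.17e-05) and ion channel genes (0.36, 2.06e-05) rose. Technical lists rose as well, ribosomal protein genes by 0.52 (adjusted p = 3.41e-06), immediate early genes of cell dissociation by 0.48 (2.28e-05) and proteasome genes by 0.21 (0.0338). HOX and Polycomb targets (-0.30, adjusted p = 0.000105) and endothelial markers (-0.27, 0.00516) fell. Across the 30 lists 14 rose and 2 fell, all with adjusted p of 0.56 or more with an estimated correlation. Without P56 replicate 2, 7 were called, at smaller medians: sarcomere 0.31, oxidative 0.37, clock 0.22, glycolysis 0.22, nuclear receptors 0.17, ribosomal 0.13 and immediate early 0.21. Among the calls that ended were those of the fatty acid (0.447), ion channel (0.0562), HOX and Polycomb (0.0649) and endothelial (0.0932) lists, the last also lost without P14 replicate 2 (0.0718). Without both P1 replicate 1 and P56 replicate 2 the fatty acid (0.417), HOX and Polycomb (0.0523), endothelial (0.0924) and proteasome (0.799) calls ended, the last also with loess offsets (0.255), and among the medians still called were 0.31 for sarcomere, 0.38 for oxidative and 0.10 for ion channel genes. With the TSS share as a covariate the fatty acid list was lower and called (0.0432), and the sarcomere (0.853), oxidative (0.104), clock (0.658), glycolysis (0.881), ion channel (0.806), HOX and Polycomb (0.0699) and 3 technical calls ended. That share also separated the P14 libraries (34.0% to 35.3%) from the P56 libraries (35.5% to 36.8%), so it cannot be told from stage. With the peak share the fatty acid list was lower and called (0.0177), the sarcomere (0.755) and ion channel (0.743) lists turned lower without passing, and the oxidative (0.0647), clock (0.66), glycolysis (0.903), endothelial (0.145) and 3 technical calls ended.

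Whether the change in the first interval differed from that in the second was tested directly, and 3 regions passed: Gm10800, Gm10801 and Gm26917, each higher at P14 than at either end. No named heart gene passed this test, so no gene was shown to change mainly before or mainly after P14. Of the regions, 2043 had an unadjusted p below 0.05. The count was 0 without P14 replicate 2 or P14 replicate 3 (1645 and 1671 at an unadjusted p below 0.05).

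In the peak table, 55 peaks rose and 60 fell from P1 to P56. Rises included a peak inside Trim7 (GRCm38 chromosome 11, 48833416 to 48835032, 1.75, adjusted p = 0.00315) and a pair near Trim27 (chromosome 13, 21172181 to 21173655, 1.82, 0.00294, 5795 bp away, and 21169395 to 21170728, 1.47, 0.0168). Others were a peak inside Mib1, a ubiquitin ligase of Notch signalling (chromosome 18, 10778866 to 10782655, 1.46, adjusted p = 0.00526), and one 6417 bp from Pllp (chromosome 8, 94702659 to 94704777, 1.46, 0.00937). Falls included a peak 5125 bp from Klra17 (chromosome 6, 129881797 to 129884681, -1.49, adjusted p = 0.00947) and one inside Ripor2 (chromosome 13, 24565210 to 24566857, -1.46, 0.0168). Further falls were peaks outside genes on chromosomes 7 (51343546 to 51345121, -1.64, adjusted p = 0.0153), 5 (133385404 to 133386676, -1.47, 0.038) and 3 (93841743 to 93845221, -1.41, 0.0374). Of the falls 52 of 60 lay outside protein-coding genes and more than 1 kb from one (Fisher's exact p = 6.28e-16). Such peaks made up 36% of all peaks. Their median change was -0.26, against 0.18 for peaks within 1 kb of a gene end, so the lean was not confined to the called falls. The rises were 21 outside, 16 inside and 18 within 1 kb of a gene end. Without both P1 replicate 1 and P56 replicate 2, 361 peaks rose and 286 fell. The peak count was 0 without P56 replicate 2 (2279 at an unadjusted p below 0.05), 8 without P1 replicate 2, 18 without P56 replicate 3, 63 without P14 replicate 3 and 649 without P56 replicate 1. The share of calls up was 47.8%, against 33.1% with library size (41 up, 83 down), 30.3% with loess offsets (10 up, 23 down) and 95.7% with the TSS table's factors (45 up, 2 down), with which the median peak was 0.31, against 0.03.

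Peaks within 5 kb of contractile and mitochondrial genes leaned the same way as the TSS. All 27 peaks near sarcomere genes had a log2 change above 0 (median 0.54, 4 called), as did 50 of 51 near oxidative genes (0.50, 1 called), and 32 of 43 near fatty acid genes (0.34, none called). The same held for 23 of 26 near glycolysis genes (0.41, none called), 25 of 39 near ion channel genes (0.22, 1 called) and 13 of 18 near fetal contractile genes (0.27, 1 called). Peaks near technical lists leaned likewise, 30 of 32 near ribosomal protein genes (0.37, none called) and 20 of 25 near immediate early genes (0.30, none called). All peaks within 1 kb of a gene end had a median of 0.18. A peak 7414 bp from Myh7 (chromosome 14, 55002040 to 55006120), chosen after its value was seen, rose by 1.36 (adjusted p = 0.00368), and one at the Myh6 side (54965341 to 54969222), also chosen then, had 0.28 (0.601). Across 8081 genes with a peak within 5 kb, TSS and peak changes from P1 to P56 correlated with Pearson's r 0.678 and Spearman's rho 0.658. Genes are not independent replicates and both tables come from the same libraries. The share of peak counts within 1 kb of a gene end was 40.3% ± 5.22 (SD, n = 3) at P1, 39.0% ± 0.931 at P14 and 43.7% ± 3.61 at P56, a difference within the spread (exact permutation p = 0.361).

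Between P1 and P14, peaks on chromosome 2 (98665793 to 98667822, 1.26, adjusted p = 0.0244) and chromosome 8 (83756290 to 83757487, 1.57, 0.0397) rose in CPM. Their unscaled counts stayed at 215 to 281 and 29 to 41 in all libraries, while peak totals ranged from 316311 to 1217798. Counts at Gm10800 were 208 to 283, so the chromosome 2 peak and that gene model may not be separate. Between P14 and P56, a peak 12390 bp from the histone gene H4c8 (chromosome 13, 23517067 to 23518654, 2.31, adjusted p = 0.0108) and the Mib1 peak (1.75, 0.00901) rose. No peak fell in either interval. Of the peaks, 1563 and 3798 had an unadjusted p below 0.05, limma-voom called 2 and 0, and the DESeq2 Wald test 2 and 0. In the first interval no peak was called without P1 replicates 2 or 3 or P14 replicates 2 or 3, and 39, 5, 10 and 1 were called without P1 replicate 1, P56 replicate 1, P56 replicate 2 and P56 replicate 3. In the second, none was called without P14 replicate 1, P14 replicate 3 or P56 replicate 2, and 16, 14, 292 and 4 were without P1 replicate 1, P1 replicate 3, P56 replicate 1 and P56 replicate 3. The timing contrast called 2 peaks, the chromosome 2 peak and one on chromosome X (143482560 to 143483626), both higher at P14. Counts at the latter were 30 to 47 in all libraries. The count of calls was 0 without P14 replicates 2 or 3, 8 without P1 replicate 1, 4 without P56 replicate 1 and 1 without P56 replicate 2.

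The intervals P14 with P1 and P56 with P1 share the P1 libraries. They shared 3 of the 4 and 581 TSS rises, against 0.0689 for independent lists. Besides Gaa, those 4 were the gene models Gm10800, Gm10801 and Gm26917, whose counts grew little with library depth, and P1 was the deepest stage. In 10 simulations of unchanged groups the mean was 0 shared, but these called a mean of 0 and 0.2 regions, so none could be shared and that 0 decides nothing. Their TSS log2 changes had r = 0.507 and a covariance of 0.0909, against 0.369 and 0.0376 in the simulations. For peaks r was 0.283 and the covariance 0.0550, against 0.410 and 0.0559, with 0 shared rises (0.00425 for independent lists). The 3 P1 libraries could not be split into groups of 2 or more, so part of the excess over independent lists may come from sharing them. Another part may come from those gene models.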

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

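The splits of the samples were fixed before the results were seen; the test of counts against library depth was chosen after them. The change from P1 to P14 differed from the change from P14 to P56, by the test of that difference, for 3 TSS regions and 2 peaks, all highest at P14. The differences in log2 change were 2.09 ± 0.308 (SE, edgeR adjusted p = 0.00338) for Gm10800, 1.70 ± 0.304 (0.0356) for Gm10801 and 1.38 ± 0.232 (0.0194) for Gm26917. They were 2.11 (edgeR adjusted p = 0.0164) for the chromosome 2 peak that starts at 98665793 and 2.62 (0.0164) for the chromosome X peak that starts at 143482560. Counts per library were 208 to 283 at Gm10800 and 215 to 281 at the chromosome 2 peak. Whether these count the same reads was not tested, so they may not be separate results. Of 100 splits of the 9 libraries, 11 called as many TSS regions for timing (highest of the others 888 against 3) and 12 as many peaks (1674 against 2), so chance could not be excluded for these counts. Splits that call so many more point to a structure of the samples, which can include their age: the highest TSS split kept the 3 P56 libraries together as its middle group, and the highest peak split set P56 replicates 2 and 3 with P1 replicate 3 there.

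The 3 gene models had counts that varied less than the library totals: 208 to 283 for Gm10800, 165 to 271 for Gm10801 and 1253 to 2583 for Gm26917. A candidate explanation is reads at repeated sequence that do not grow with depth. Within stages the log2 count rose with the log2 total at slopes of 0.25 ± 0.141 (SE) for Gm26917, 0.153 ± 0.0527 for Gm10801 and 0.0685 ± 0.0892 for Gm10800, the highest being 0.25, where 1865 regions with a mean count of at least 100 had a median of 0.967. P14 was the shallowest stage, so such counts yield higher CPM there. A change with age itself stays open and was not tested.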

How the results depend on the processing

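The loess offsets, both enrichment covariates, the thinning, the fits without both P1 replicate 1 and P56 replicate 2 and the DESeq2 size factors for lists were chosen after the results were seen; the other alternatives were planned. Except where fewer regions, libraries or counts entered or a stricter threshold was set, the cause of a change was not tested. A list or gene is said to turn or change direction only where it was called in the full result or under the alternative; turns of lists called in neither are not counted. Counts are of calls at an adjusted p below 0.05 against 853, 4, 1 and 3 TSS regions and 115, 2, 2 and 2 peaks for P56 with P1, P14 with P1, P56 with P14 and timing, and 16, 7 and 16 lists.

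Dropping the filter kept every count within 1.5 times, and DESeq2's size factors did so except for P56 with P14 at the TSS (0; 3345 at an unadjusted p below 0.05) and timing (1). Library size gave 11 TSS regions for P56 with P14 and 0 peaks for P14 with P1 (1508 unadjusted). The other table's factors gave 2504 and 22 TSS regions for P56 with P1 and P56 with P14, 47 peaks for P56 with P1, and 0 peaks in each of the other 3 contrasts (1889, 3830 and 2069 unadjusted). A mean count of at least 20 left 270, 2, 0 and 1 TSS regions and 44, 0, 0 and 1 peaks (for the zeros 2229 TSS regions, and 923 and 2061 peaks, unadjusted), and 9 and 1 lists for P56 and P14 with P1.

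The DESeq2 Wald test called 292, 1 and 0 TSS regions for P56 with P1, P14 with P1 and timing (917 unadjusted for the last), and 0 and 1 peaks for P56 with P14 (2381 unadjusted) and timing. Limma-voom called 1, 0 and 0 TSS regions for P14 with P1, P56 with P14 and timing (3082 and 1979 unadjusted for the zeros), 49 peaks for P56 with P1, and 0 for P56 with P14 and timing (3674 and 2178). Fits of 2 stages alone called 182, 7 and 30 TSS regions and 48, 7 and 19 peaks. An adjusted p below 0.01 left 88, 0 and 1 TSS regions for P56 with P1, P56 with P14 and timing and 13, 0, 1 and 0 peaks; an adjusted p below 0.05 with a log2 change beyond 1 left 421 and 2 TSS regions for P56 and P14 with P1. With an estimated inter-gene correlation 0, 0 and 0 lists were called and with fry 1, 1 and 0. No called list changed direction under either. Against random lists matched on abundance, the medians of 9, 5 and 10 lists lay above the central 95% and those of 3, 2 and 5 below it. Of 39 list calls, 39 were kept with DESeq2's size factors, 36 with library size, 24 with loess offsets, 22 with a mean count of at least 20 and 18 without both P1 replicate 1 and P56 replicate 2. Of 59 calls of named genes, 54 were kept with DESeq2's size factors, 50 with library size, 32 with the Wald test, 25 with loess offsets and 24 without both libraries, and no called gene changed direction. Some of the calls not kept with the Wald test, those of the named falls among them, had no adjusted p there. Without both libraries 7 named genes not called in the full result gained a call. Meis1 was among them, for which those libraries held the lowest P1 and the highest P56 value.

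The labels give the stages the same replicate numbers without saying that a number joins samples. Deviations from the stage means correlated at -0.07 to 0.219 for the same number and -0.27 to 0.249 for other numbers at the TSS, and at -0.18 to 0.445 against -0.50 to 0.489 for peaks, so the numbers were not taken to pair the samples. With the replicate number as a block (replicate block) the fit called 1982, 12, 76 and 5 TSS regions and 684, 18, 41 and 10 peaks. Of the lists, mitosis for P56 with P1 lost its call (0.056) and fetal contractile (0.0267), glycolysis (0.048) and growth factor genes (0.0491) for P14 with P1 gained one, and 26 of 104 named genes not called otherwise were called; no other call of a list or named gene changed.

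Loess offsets left 240, 1 and 1 TSS regions for P56 with P1, P14 with P1 and timing, and 33, 0, 0 and 1 peaks (1638 and 3474 unadjusted for the zeros), with 3 lists for P14 with P1. The direction turned for cardiac transcription factors (0.982), chromatin regulators (0.825) and extracellular matrix (0.0413) in P56 with P1. With a mean count of at least 20 it turned for mitosis (0.99). Thinning to the shallowest library called 0 in all 8 contrasts, so the calls depended on depth. There 3072, 1686, 1085 and 850 TSS regions and 2042, 979, 1170 and 797 peaks had an unadjusted p below 0.05. With no change, a share of 0.05 of those tested would have one by chance. Only the counts for P56 with P1 exceeded that share, so the other counts do not show changes hidden by depth.

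Without both P1 replicate 1 and P56 replicate 2 the fits called 245, 15 and 10 TSS regions for P14 with P1, P56 with P14 and timing, 647, 993 and 135 peaks for P56 with P1, P14 with P1 and timing, and 7 and 9 lists for P56 with P1 and P56 with P14. Directions turned for fatty acid oxidation (0.63), cardiac transcription factors (0.0949) and nuclear receptors (0.985) in P56 with P1 and for sarcomere genes in P14 with P1 (0.538).

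Both enrichment covariates lowered the count for P56 with P1 at the TSS and left no peak for P56 with P14; in the other contrasts the peak share raised the count and the TSS share lowered it. The peak share, tried first on the peak table, gave 203, 318, 3 and 9 TSS regions, of which 29 rises and 9 falls from P1 to P56 were shared with the full result, 710, 854, 0 and 26 peaks (1843 unadjusted for the 0), and 6 and 2 lists for P56 with P1 and P56 with P14. The TSS share separates the libraries of each stage from those of the others, and so cannot be told from stage in any comparison. It gave 0, 0, 0 and 1 TSS regions (1289, 2469 and 977 unadjusted), 0 peaks in every contrast (1087, 2629, 648 and 3669), and 16 and 2 lists for P14 with P1 and P56 with P14. The TSS share turned the direction of 30 of 90 list results and the peak share of 26.

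With the TSS share, the lists that turned in P56 with P1 were mitosis (0.502), checkpoint (0.00121), sarcomere (5.96e-05), fetal contractile (0.377), fatty acid oxidation (2.29e-08), oxidative phosphorylation (0.0126), glycolysis (0.00697), ion channels (0.0456), cardiac transcription factors (0.000252), nuclear receptors (0.0178), clock (0.000448), chromatin regulators (0.0276), ribosomal (0.0395), proteasome (0.0725) and immediate early genes (0.0055). In P14 with P1 they were sarcomere (1.23e-08), fatty acid oxidation (3.85e-09), oxidative phosphorylation (3.67e-06), glycolysis (0.000153), ion channels (0.00206), chromatin regulators (0.0121), ribosomal (0.00099), proteasome (0.0456) and immediate early genes (0.000252). In P56 with P14 they were checkpoint (0.407), fatty acid oxidation (0.0432), cardiac transcription factors (0.279), chromatin regulators (0.563), proteasome (0.624) and immediate early genes (0.881).

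With the peak share, the lists that turned in P56 with P1 were mitosis (0.983), checkpoint (0.0177), sarcomere (0.147), fatty acid oxidation (0.000202), oxidative phosphorylation (0.971), glycolysis (0.596), ion channels (0.162), cardiac transcription factors (0.000457), nuclear receptors (0.0647), clock (0.0201), chromatin regulators (0.39), ribosomal (0.37), proteasome (0.483) and immediate early genes (0.0647). In P14 with P1 they were sarcomere (0.152) and fatty acid oxidation (0.0201). In P56 with P14 they were checkpoint (0.38), sarcomere (0.755), fetal contractile (0.971), fatty acid oxidation (0.0177), ion channels (0.743), cardiac transcription factors (0.0789), nuclear receptors (0.903), chromatin regulators (0.591), proteasome (0.552) and immediate early genes (0.454). Over its 19 alternatives the sarcomere list in P56 with P1 had adjusted p of 1.63e-26 to 0.56, and the oxidative list 3.07e-19 to 0.971.

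Leaving out 1 library at a time, the TSS fits called 148 (without P56 replicate 2) to 1776 (without P56 replicate 1) regions for P56 with P1, 0 (P14 replicate 2) to 9 (P56 replicate 2) for P14 with P1, 0 to 289 (P56 replicate 1) for P56 with P14, and 0 to 4 for timing. For peaks they called 0 (P56 replicate 2) to 649 (P56 replicate 1), 0 to 39 (P1 replicate 1), 0 to 292 (P56 replicate 1) and 0 to 8 (P1 replicate 1). Lists ranged over 11 to 19 for P56 with P1, 3 (P14 replicate 2) to 14 (P1 replicate 3) for P14 with P1, and 7 (P56 replicate 2) to 17 for P56 with P14. Of the single lists the sarcomere list in P14 with P1 turned, without P1 replicate 1 (2.87e-06 to 0.593 over the libraries left out), 45 calls were lost and 24 gained over the 3 comparisons. In P56 with P1 the range was 2.58e-10 to 0.123 for fatty acid oxidation, 0.000761 to 0.779 for cardiac transcription factors and 1.21e-05 to 0.146 for nuclear receptors. In P56 with P14, calls were lost without P14 replicate 1 (checkpoint 0.087, cardiac transcription factors 0.0524, chromatin regulators 0.0902, proteasome 0.312), P14 replicate 3 (cardiac transcription factors 0.0737) or P56 replicate 2 (checkpoint 0.526, fetal contractile 0.0553, cardiac transcription factors 0.52, chromatin regulators 0.431, proteasome 0.779). The exact p of the promoter share ranged from 0.146 to 0.711 and was 0.336 with 5 kb; peaks within 50 kb of a gene in place of 5 kb lowered the correlation of TSS and peak changes from 0.678 to 0.629.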

Other observations

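The tests of the abundance trend, of the libraries that stood apart and of other cell types were chosen after the results were seen; the clock test and the splits were fixed before. For the sarcomere and oxidative lists the bound that would have excluded an explanation was made stricter after the values were seen, from no overlap between the stages to a gap wider than the spread within them. Under the earlier bound the 2 libraries that stood apart would have been excluded as the cause of the oxidative list's rise, since without them the highest P1 library (5.51 log2 CPM) lay below the lowest P56 library (5.57). The change of bound turned that outcome into one that cannot be told apart.

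Peaks near HOX and other Polycomb targets leaned the same way as their TSS from P1 to P14: all 6 peaks within 5 kb had a log2 change above 0, with a median of 0.57 and no peak called. Counts at the Myh7 TSS were 60.8 to 96.7 per 100 counts of the peak 7414 bp away in every library. TSS and peak changes correlated across 8081 genes with r = 0.515 from P1 to P14 and 0.648 from P14 to P56.

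From P1 to P56, rises lay at strongly covered TSS regions (562 of 581 above the median abundance) and falls at weak ones (43 of 272). With loess offsets 17.7% of the rises and 16.5% of the falls stayed called. Median folds went from 0.88 to 0.63 (SE 0.210 and 0.197) and from -1.31 to -1.06 (SE 0.340 and 0.339), with 580 of 581 and 272 of 272 in the same direction. The folds thus shrank at a like SE, and most of their size remained. These regions were selected as called in the same data, so the kept direction and size do not weigh against an effect of enrichment. The loss of calls met the bound set for a higher share of signal over background in the P56 libraries. That bound counts calls and does not show that this share caused the folds. The sarcomere and oxidative medians shrank from 0.82 and 0.69 to 0.56 and 0.48 with these offsets (adjusted p = 2.03e-11 and 1.39e-10) and to 0.23 and 0.21 without P1 replicate 1 and P56 replicate 2 (0.00226 and 0.00237), without a gap between the P56 and P1 libraries wider than their spread, so for both lists neither that share nor those libraries can be told apart from a change with age. Fewer nuclei of other cell types at P56 cannot be told apart either: 4 of 7 lists of their markers, from Vwf for endothelium to Col1a1 for fibroblasts as most abundant (-0.18 and 0.50, adjusted p = 0.497 and 0.0926), lay below the median of matched random lists, after a sort on Pcm1 that would remove such nuclei, and of the fibroblast and the smooth muscle markers 5 each are held by another list. A change with age stays open and was not separable from the enrichment of the libraries.

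Splits of the libraries of each comparison into groups of 3 number 10, too few for a share under 0.05. Counting the real split, 1 gave as many TSS regions in each comparison (853 against 191 in the highest other for P56 with P1, 4 against 0 for P14 with P1, 1 against 0 for P56 with P14), and 1 as many peaks (115, 2 and 2 against 0 in each). For the lists 4, 7 and 2 splits gave as many calls (16, 7 and 16 lists against 17, 15 and 16 in the highest other). The median change of the sarcomere list was 0.82 against 0.94 in the largest other split, and that of the oxidative list 0.69 against 0.66.

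A hypothesis for the clock list, higher at P56 than at P1, was a difference in the time of day at collection, which the labels do not give. It predicts a fall in the genes of the opposite phase. The 10 targets of the clock's activators had a mean log2 change of 0.64 ± 0.343 (SD) and the 6 genes of the opposite phase 0.23 ± 0.351. The permutation p for the difference was 0.0366, over 100000 permutations of genes between the groups. Genes measured in the same libraries are not independent replicates, so this p says nothing of the spread between libraries. The opposite-phase mean was lower than that of the targets but not below 0. With loess offsets the means were 0.40 and 0.10. The time of day cannot be told apart from a change with age, since no value here decides between them.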
